A study of Homo sapiens with 4 samples.

How the data were processed

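Myla cells were transduced with lentivirus carrying hairpin RNA against FOXM1 or a scrambled hairpin, with 10 uL of virus medium in 1 mL of culture. From each group 2 libraries were sequenced. Per the labels' protocols, RNA came from a column kit and libraries from a SMARTER mRNA kit, and the submitters describe the samples as biological replicates. The labels do not say whether the cultures were transduced separately, so p-values measure only the spread between these libraries, which may be technical.

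The authors deposited one table of FPKM (fragments scaled by gene length and library size) for 58735 genes and 4 libraries, with the gene length the authors used, per the file headers. The aligner, counter and strand setting are not given in the sources used here. The submitters' processing notes name the mouse builds GRCm38 and mm10, while all 58735 gene identifiers, starts, ends and chromosomes in the table equal those of human GENCODE release 29 (GRCh38), and coordinates here are those of the table. The columns carry short names, and the 2 named sh0 were taken as shControl and the 2 named sh1 and sh2 as shFOXM1. The sh0 names have a replicate number added, while sh1 and sh2 have none. Whether sh1 and sh2 are replicates of the same hairpin or different hairpins is not stated. The spread within shFOXM1 may therefore hold a difference between hairpins. There were 0 columns of other samples.

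FPKM multiplied by gene length gave whole reads for 100% of values within 0.001 read. Recovered totals were 14147084 (shControl 1), 14778639 (shControl 2), 15017728 (shFOXM1 1) and 14680094 (shFOXM1 2), and the totals that the deposited FPKM implied differed from them by 0.319, -0.173, -1.44 and 3.8%. Median-of-ratios factors of the FPKM values were 1 in every library. At these depths 1 read in a gene of 1 kb was worth between 0.0656 and 0.0705 FPKM. Protein-coding genes held 97.4 to 97.5% of reads, and mitochondrial genes 5.93 and 5.88% in shControl and 5.72 and 4.98% in shFOXM1. The replicates of each group differed by more than sampling noise (chi-square per degree of freedom 3.96 for shControl and 37.1 for shFOXM1, over genes with at least 20 reads in the pair), so each was counted as 1 sample.

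Genes with at least 1 FPKM in at least 2 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3 (empirical Bayes with a trend, two-sided, Benjamini-Hochberg adjusted p under 0.05). Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. A difference of 2 against 2 has a smallest two-sided exact permutation p of 0.333, so single values were given without one. Lists of genes were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, which asks whether a list's genes move on balance one way and compares them with no other genes. The estimated correlation between members was 0.593 for the mitosis list, 0.232 for S phase and 0.774 for glycolysis. Where members vary together this much, camera's p at the preset is too small. For the MuvB and DREAM complex list and the cytosolic ribosomal protein list the estimates were only 0.0607 and 0.00637. Their unadjusted camera p still rose with the estimate, from 0.00239 to 0.131 and from 0.0093 to 0.109. The estimates themselves are uncertain, as they come from 4 libraries. With an estimate, camera also judges each list on the few degrees of freedom that 4 libraries leave. A larger p with the estimate is therefore not due to correlated members alone. The 23 lists, the test, and the rule for named genes were fixed before the data were examined. The rule took FOXM1, then the 12 largest changes per direction among genes past the test. As fewer than 5 passed, it took the 8 genes per direction with the smallest unadjusted p, a mean of at least 1 FPKM and groups that did not overlap, and up to 4 measured members per list with the smallest unadjusted p. AURKA and the genes of the closing section outside the rule were chosen after their values were seen. One gene that the rule took is not reported here.

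Data were simulated for 12033 genes with the spread of the real libraries, pooled over both groups. Changed genes were drawn only among those with higher read counts. The limma test recovered 22 of 100 genes changed by 1 on the log2 scale and 85 of 100 changed by 2, with 1 false call. With no simulated change limma called 0 genes and camera at the preset correlation 0 lists, and with the mitosis list lowered by 0.5 camera called 1 list. The simulated genes varied independently of each other. The simulation therefore cannot show how often camera calls unchanged lists whose genes vary together. Nor does it cover low genes or groups of unequal spread, as the real groups were.

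Alternatives fixed beforehand were pseudocounts of 0.1 and 0.01, no filter, a mean of at least 5 FPKM, quantile normalization, median-of-ratios scaling, a replicate block, empirical Bayes without a trend or robust, and each library left out. Voom on the recovered reads, voom with library weights, scaling by the total of recovered reads and only genes of at least 200 bases were chosen after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.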

Results

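Messenger RNA was sequenced from Myla cells, a cell line of mycosis fungoides (a lymphoma of T cells in the skin), after transduction with a lentivirus. One group received short hairpin RNA against FOXM1 (shFOXM1, 2 libraries) and the other a scrambled hairpin (shControl, 2 libraries). Whether the 2 shFOXM1 libraries carried the same hairpin is not stated. RNA was taken 72 h after the medium was changed, which was done 24 h after transduction. The whole reads behind the deposited FPKM values numbered 14147084 and 14778639 in shControl 1 and 2, and 15017728 and 14680094 in shFOXM1 1 and 2. The comparison asked which genes differ in level when FOXM1, a forkhead transcription factor of dividing cells, is knocked down.

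FOXM1 itself was lower in both shFOXM1 libraries. Its level was 26.5 and 27.6 FPKM in shControl 1 and 2 and 9.27 and 5.59 FPKM in shFOXM1 1 and 2, or 27.1 ± 0.784 against 7.43 ± 2.6 FPKM (mean ± SD, n = 2 each), a ratio of shControl to shFOXM1 of 3.65. The gene (ENSG00000111206) lies on the minus strand of chromosome 12 from 2857681 to 2877155, and its values rested on 1845, 1998, 672 and 417 reads in the same order. The fitted log2 fold change was -1.77 (SE 0.23), which missed the threshold over all genes (limma, adjusted p = 0.173). Without shFOXM1 1 it was -2.09 with an adjusted p of 0.0122, and without shFOXM1 2 it was -1.45 with an adjusted p of 0.0331 in the same limma test, where the spread comes from the controls alone. Limma gave an adjusted p of 0.753 without shControl 1 and 0.631 without shControl 2.

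The genes of cell division were lower in the shFOXM1 libraries as groups. All 44 measured members of the list of G2/M and mitosis genes of the FOXM1 programme had a lower mean in shFOXM1, with a median log2 fold change of -0.51, and for 43 of them both shFOXM1 libraries lay below both shControl libraries. TOP2A, the topoisomerase that untangles chromosomes, was at 98.8 ± 1.14 FPKM in shControl and 53.8 ± 0.265 in shFOXM1 (n = 2 each). CENPA, the histone variant of the centromere, was at 17.3 ± 0.61 and 8.57 ± 0.797 FPKM, and CDK1, the kinase that drives entry into mitosis, at 33.9 ± 1.24 and 17.9 ± 3.25 FPKM. The exception was AURKA, a mitotic kinase, with a log2 fold change of -0.07 and overlapping groups. None of the members passed limma's test over all genes, while 33 were lower past the threshold adjusted over the list alone. The list fell relative to the other genes tested (camera at the preset correlation, adjusted p = 8.4e-20). That value takes members as nearly independent, while their estimated correlation was 0.593. With the estimated correlation, and the few degrees of freedom it then uses, camera gave an unadjusted p of 0.16 and an adjusted p of 0.738.

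All 33 measured genes of DNA replication and S phase were likewise lower on average, with a median log2 fold change of -0.63. UHRF1, which helps maintain DNA methylation in replicating cells, was at 60.8 ± 1.48 FPKM in shControl and 28.3 ± 0.298 in shFOXM1, and TK1, the thymidine kinase of S phase, at 91.8 ± 3.25 and 43.7 ± 1.61 FPKM. Of the 33 genes, 0 passed over all genes in limma and 29 were lower adjusted over the list alone. The list fell relative to the other genes (camera at the preset correlation, adjusted p = 8.4e-20). With the estimated correlation of 0.232 camera gave an unadjusted p of 0.0652 and an adjusted p of 0.738.

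**Figure D1:**
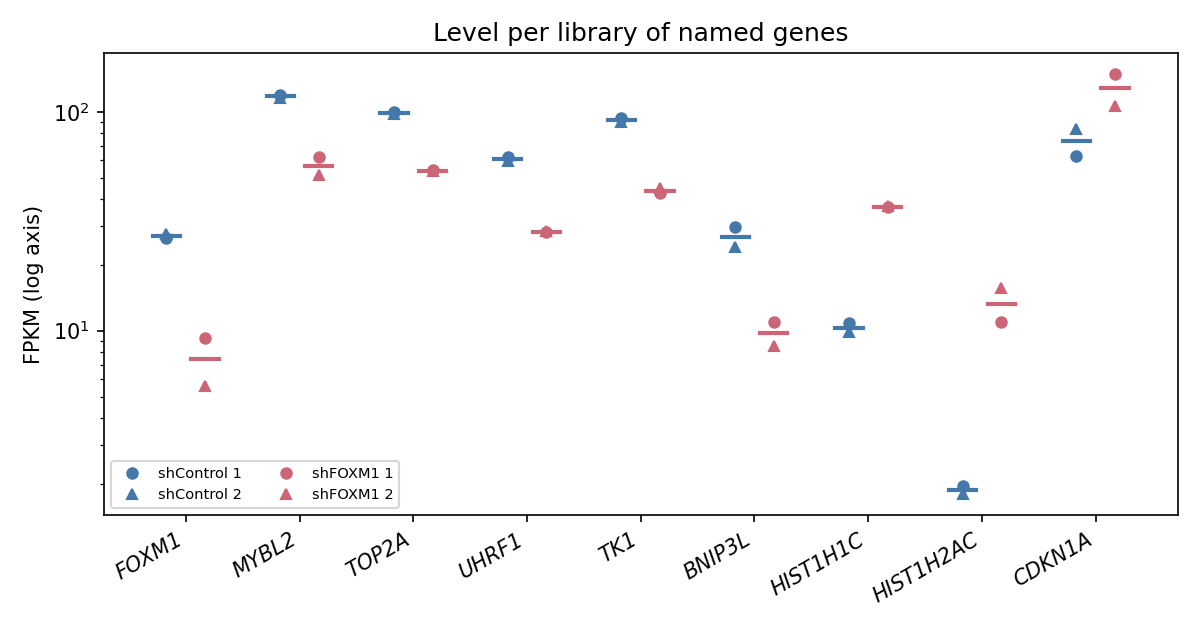
FPKM on a log axis for named genes in each library. Circles are replicate 1 and triangles replicate 2, blue for shControl and red for shFOXM1, and each bar is a group mean of 2 libraries. FOXM1 had means of 27.1 and 7.43 FPKM and HIST1H1C of 10.3 and 36.9 FPKM in shControl and shFOXM1.

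DNA repair genes fell as a list by a median log2 value of -0.45 over 24 measured members (camera, adjusted p = 1.27e-06), with an adjusted p = 0.738 with an estimated correlation. Of these, 20 were lower and 4 higher by sign. LIG1, the DNA ligase of replication, was at 21.6 ± 0.166 FPKM in shControl and 12.8 ± 1.14 in shFOXM1, and RAD54L, which acts in homologous recombination, at 12 ± 0.296 and 7.13 ± 0.499 FPKM. In limma 0 members passed over all genes and 7 were lower adjusted over the list alone. The MuvB and DREAM complex list, which holds FOXM1 itself, fell by a median of -0.24 over 12 members (camera, adjusted p = 0.011), with an adjusted p = 0.738 with an estimated correlation. MYBL2, the MYB protein that joins MuvB, was at 118 ± 3.41 and 56.6 ± 7.64 FPKM, and 4 members, FOXM1 among them, were lower adjusted over the list alone against 0 over all genes. Without FOXM1 the 11 other members had a median of -0.20 and an unadjusted camera p of 0.0126, or 0.138 with an estimated correlation.

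Genes of glycolysis and hypoxia fell as a list, by a median log2 value of -0.47 over 27 measured members, 25 of them lower by sign (camera, adjusted p = 1.69e-05). The adjusted p = 0.902 with an estimated correlation. BNIP3L, a mitophagy receptor that hypoxia induces, was at 26.9 ± 3.92 FPKM in shControl and 9.76 ± 1.75 in shFOXM1 and was the only member lower past the threshold adjusted over the list alone, with 0 over all genes in limma. LDHA, the lactate dehydrogenase of glycolysis, was at 298 and 263 FPKM in shControl 1 and 2 and at 202 and 100 FPKM in shFOXM1 1 and 2. The list's median against the control mean was -0.14 in shFOXM1 1 and -0.74 in shFOXM1 2, and shControl 2 lay -0.14 from shControl 1. The cytosolic ribosomal protein list moved by a median of -0.06 over 49 members (camera, adjusted p = 0.0338), with an adjusted p = 0.738 with an estimated correlation and 0.534 after quantile normalization, and 0 members passed in limma over all genes or adjusted over the list alone. Its adjusted camera p was 0.148 without shControl 1, 0.137 without shControl 2 and 0.303 without shFOXM1 1.

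**Figure D2:**
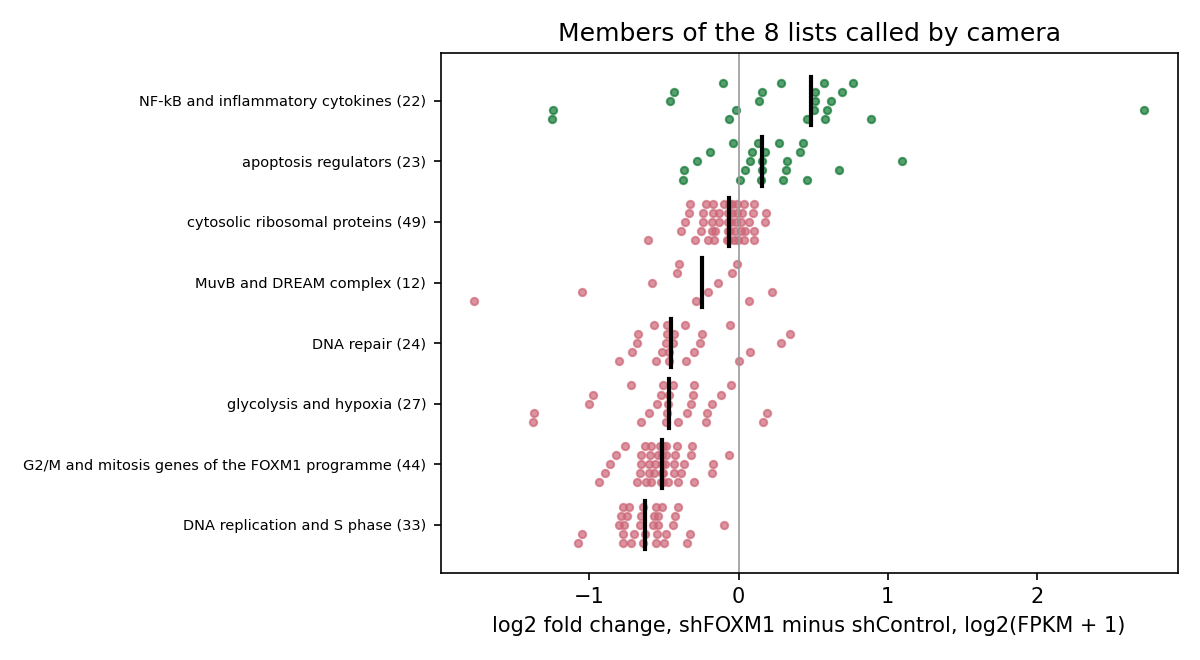
Log2 fold change on the log2(FPKM + 1) scale, shFOXM1 minus shControl, of each measured member of the 8 lists that camera called. Dots are genes, red where the list median was negative and green where it was positive, and black bars are list medians, which ran from -0.63 for DNA replication and S phase to 0.48 for NF-kB and inflammatory cytokines.

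The lists of NF-kB genes and of apoptosis regulators were higher. NF-kB and inflammatory cytokines rose relative to other genes with a median log2 fold change of 0.48 over 22 measured members, 15 of them higher by sign (camera, adjusted p = 0.0338). The adjusted p = 0.902 with an estimated correlation. NFKB2, an NF-kB subunit, was at 167 ± 7.76 FPKM in shControl and 273 ± 53.7 in shFOXM1, while the chemokine CXCL10 was at 23.2 ± 0.611 and 9.23 ± 0.19 FPKM. In limma 0 members passed over all genes, and 5 were higher and 2 lower adjusted over the list alone. The NF-kB list's median against the control mean was 0.18 in shFOXM1 1 and 0.35 in shFOXM1 2, and shControl 2 lay 0.15 from shControl 1. Apoptosis regulators rose by a median of 0.16 over 23 members, 18 of them higher by sign (camera, adjusted p = 0.042), with an adjusted p = 0.902 with an estimated correlation. Against the control mean its median was 0.21 in shFOXM1 1 and 0.10 in shFOXM1 2, and shControl 2 lay 0.08 from shControl 1. The list holds genes that promote cell death as well as genes that restrain it. BCL2L1, which restrains cell death, was at 47.9 and 52.9 FPKM in shControl 1 and 2 and at 82.8 and 143 FPKM in shFOXM1 1 and 2, and 0 members passed over all genes or adjusted over the list alone. Camera's adjusted p for the NF-kB list was 0.148 without shControl 1 and 0.167 without shFOXM1 2, and for the apoptosis list 0.214 without shControl 1 and 0.344 without shFOXM1 1.

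The other 15 lists were not called by camera. p53 targets and cell cycle inhibitors had a median of 0.16 over 24 members (camera, adjusted p = 0.17), 17 of them higher and 7 lower by sign. CDKN1A, the p21 inhibitor of cell cycle kinases, was at 73.5 ± 14.6 and 128 ± 30.6 FPKM. CDKN2C, another cell cycle inhibitor, went the other way, at 9.6 ± 0.808 and 4.92 ± 1.56 FPKM. At an unadjusted limma p under 0.05, 3 members were higher and 2 lower. The unfolded protein and integrated stress response list had a median of -0.19 (camera, adjusted p = 0.0579). The interferon response had a median of 0.10 but a mean of -0.07 and a camera direction downwards (adjusted p = 0.979). Adjusted over the list alone, 4 of its members were lower, IFIT2 among them, and 1 was higher, BST2. T cell identity genes had a median of 0.02, a mean of -0.05 and a camera direction downwards (adjusted p = 0.92). The cutaneous T cell lymphoma and Th2 markers had a median of -0.01, a mean of -0.02 and a camera direction upwards (adjusted p = 0.993), with TNFRSF8 and DNM3 lower and BATF higher adjusted over the list alone. The camera adjusted p was 0.645 for JAK-STAT and cytokine receptor signalling and 0.645 for heat shock and immediate early response, where 3 members were higher and 2 lower adjusted over the list alone. It was 0.593 for cytotoxic effectors, 0.806 for cholesterol synthesis, 0.92 for nuclear genes of oxidative phosphorylation and 0.26 for mitochondrially encoded genes. Among these 15 lists 0 members passed limma's test over all genes, and camera with an estimated correlation and fry each called 0 of all 23 lists, with 0 and 5 lists at an unadjusted p under 0.05.

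Markers of other cell types were mostly under the level tested. The measured members were 2 of 10 for B cells and plasma cells, 1 of 10 for monocytes and macrophages, 2 of 10 for fibroblasts and endothelium and 3 of 10 for keratinocytes and epithelium, and camera's adjusted p for these lists was 0.902, 0.993, 0.54 and 0.986. Median FPKM over each list was at most 0.0448 in either group. MZB1, a chaperone of plasma cells, was at 47.2 ± 1.44 FPKM in shControl and 42.7 ± 1.58 in shFOXM1. COL3A1, a collagen, was at 24.5 and 22.7 FPKM in shControl 1 and 2 and at 45.1 and 15.9 FPKM in shFOXM1 1 and 2.

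**Figure D3:**
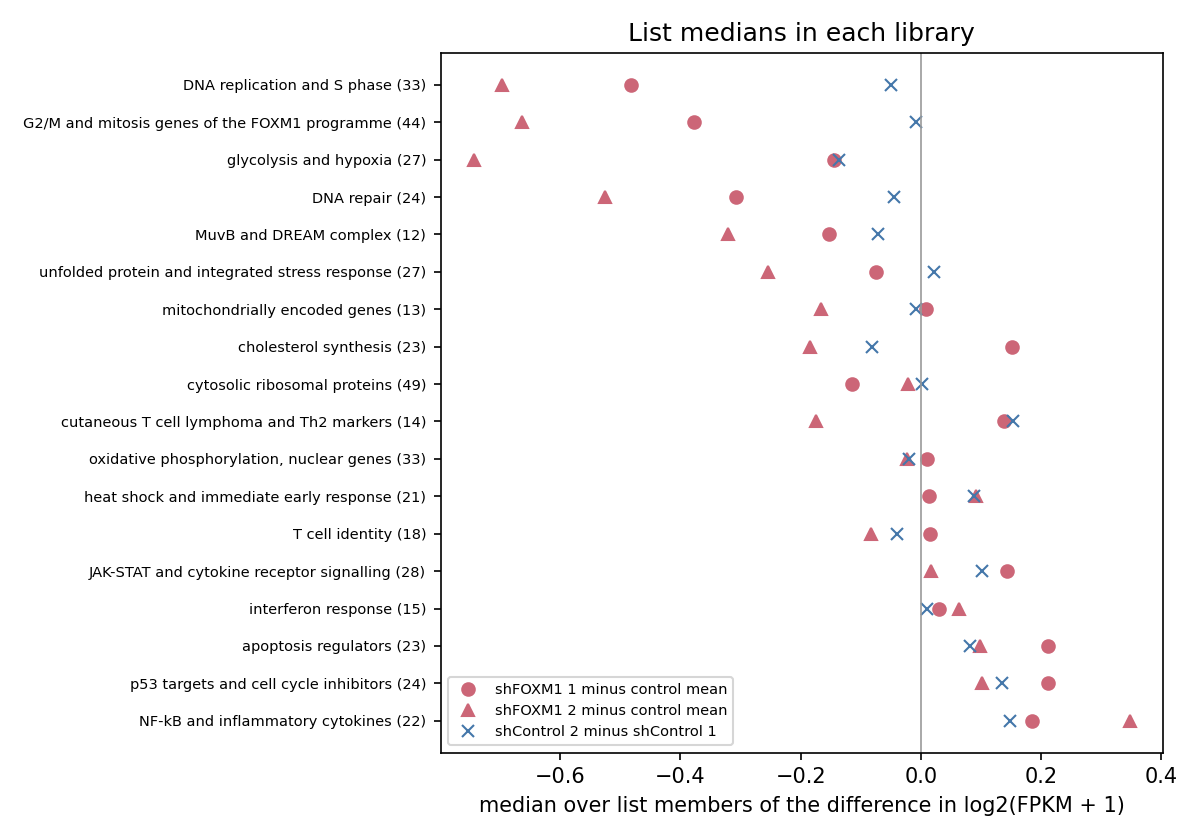
Median over the measured members of each list of at least 10 genes (number in brackets) of the difference in log2(FPKM + 1). Red circles and triangles are shFOXM1 1 and shFOXM1 2 minus the control mean, and blue crosses are shControl 2 minus shControl 1. The S phase list lay at -0.48 and -0.70 in the 2 shFOXM1 libraries.

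Over single genes, limma's test called 0 genes higher and 0 lower of 12033 tested, with 1061 higher and 1082 lower at an unadjusted p under 0.05, where chance gives 602 in all. Voom on the recovered reads also called 0 genes, with 1188 higher and 1276 lower at an unadjusted p under 0.05, and voom with library weights, chosen after seeing the data, called 25 genes higher and 9 lower. Both shFOXM1 libraries lay above or below both shControl libraries for 6396 genes, or 53.2%. The share without any effect is 33.3% if all libraries vary alike. It is higher where the shControl libraries lie closer together than the shFOXM1 libraries, as here. The genes with the smallest unadjusted p, none past the test (adjusted p = 0.173 for each), included higher levels of HIST1H1C, a linker histone, at 10.3 ± 0.662 FPKM in shControl and 36.9 ± 0.343 in shFOXM1. HIST1H2AC, a core histone, was at 1.87 ± 0.11 and 13.3 ± 3.34 FPKM, and OPTN, an autophagy receptor, at 1.91 ± 0.147 and 5.85 ± 0.0539 FPKM. IZUMO4 was at 3.45 ± 0.306 and 17 ± 3.87 FPKM, YPEL2 at 11 ± 0.37 and 24.8 ± 1.78 FPKM and NKX2-8 at 11.7 ± 0.0662 and 23.9 ± 0.49 FPKM. On the lower side, beside UHRF1, TK1 and CXCL10, IMPA2 was at 7.62 ± 0.123 and 2.96 ± 0.0869 FPKM, SNHG25 at 18.9 ± 1.22 and 8.14 ± 0.167 FPKM, and the pseudogene AC112777.1 at 20 ± 0.415 and 9.06 ± 0.351 FPKM. The 4 other genes taken by the same rule rested on few reads: SNORA9B on 1 read in each shControl and 9 in each shFOXM1 library, RNY1P13 on 0, 0, 4 and 5 reads, RNU6-850P on 13, 18, 2 and 2 reads, and SNRPGP2 on 8, 10, 0 and 0 reads. Histone genes, pseudogenes and small RNA have near-identical copies, so their reads are uncertain.

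The shFOXM1 libraries differed more from each other than the shControl libraries did. The SD over genes of the log2 difference was 0.263 between the shControl libraries and 0.424 between the shFOXM1 libraries. With shFOXM1 1 left out, limma called 1360 genes higher and 1744 lower, and with shFOXM1 2 left out 281 and 355, in fits that take the lone library to vary as the controls did.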

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

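The voom fits, the scaling by recovered reads and the limit on gene length were chosen after the results were seen; the other alternatives were planned. Limma or voom called 0 genes in either direction under every alternative except 3. Leaving out single libraries gave 0 to 1360 genes higher and 0 to 1744 lower, with FOXM1 from -2.09 to -1.45, and the calls came only when an shFOXM1 library was left out, where the spread is that of the controls alone. Voom with library weights, which gave the shFOXM1 libraries 0.392 and 0.391 and the shControl libraries 2.56 and 2.55, called 25 genes higher and 9 lower, with FOXM1 at -1.89. FOXM1's direction was the same in all alternatives, and its adjusted p ranged from 0.0122 to 0.753. Median-of-ratios scaling moved nothing because its factors were 1. The planned count tests for a table of raw counts were not run, since the table holds FPKM. Depth limits SNORA9B, RNY1P13, RNU6-850P and SNRPGP2, which rest on 18 reads or fewer.

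Camera called 8 lists, 5 without a trend, 0 with an estimated correlation, 0 by fry, and 5 to 8 when single libraries were left out. Libraries with the same replicate number shared little deviation from their group means (correlation 0.0421 over genes, 2 pairs). This cannot show whether the cultures were paired, which the labels do not say. The replicate block called 0 genes and 7 lists, where the ribosomal list had 0.0789 and the cutaneous T cell lymphoma list turned direction at 0.96. With an estimated correlation the adjusted p was 0.738 for the mitosis, S phase, DNA repair, MuvB and ribosomal lists and 0.902 for the NF-kB, apoptosis and glycolysis lists. By fry it was 0.166 for the first 5 and 0.506 for the other 3. Apoptosis had 0.191 with no filter, and NF-kB and apoptosis 0.0581 at a mean of at least 5 FPKM. Without a trend NF-kB had 0.0544, apoptosis 0.0632 and ribosomal 0.0669, and ribosomal had 0.534 after quantile normalization. With single libraries left out the adjusted p ran from 0.0021 to 0.167 for NF-kB, 0.00209 to 0.344 for apoptosis and 6.03e-05 to 0.303 for ribosomal proteins. The cause was not tested. Over lists and alternatives, 374 of 437 values kept direction and side of the threshold, 7 passed it newly, 31 lost it and 25 turned direction.

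The directions that turned belonged to lists that were not called. The cutaneous T cell lymphoma list turned at 0.977 with no filter, 0.978 after quantile normalization, 0.961 without a trend, 0.911 by fry and 0.993 with genes of at least 200 bases. Interferon turned at 0.216 at a mean of at least 5 FPKM, where its median was 0.20, and at 0.878 by voom with library weights. With no filter the cytotoxic, fibroblast and keratinocyte lists turned at 0.981, the keratinocyte list turned at 0.988 by voom with library weights and the monocyte list at 0.997 by voom. With single libraries left out, adjusted p ran from 0.541 to 0.89 for cutaneous T cell lymphoma, 0.241 to 0.95 for JAK-STAT, 0.0771 to 0.959 for cholesterol, 0.649 to 0.822 for monocyte, 0.584 to 0.95 for keratinocyte, 0.784 to 0.931 for interferon, 0.184 to 0.978 for B cell and 0.11 to 0.964 for fibroblast lists. Log2 fold changes then ran from -0.32 to 0.30 for CSF1R, -0.21 to 0.10 for TP63, -0.84 to 0.63 for CDH1, -0.11 to 0.70 for GZMM, -0.54 to 0.91 for COL3A1 and -1.03 to 1.70 for CD79A. CD79A was also at -0.017 and -0.147 with pseudocounts 0.1 and 0.01, -0.13 by voom and -0.13 by voom with library weights. CSF1R was at 0.004 under scaling by recovered reads, 0.006 by voom and 0.008 by voom with library weights. The cause was not tested. Over named genes and alternatives, 1464 of 1610 values kept direction and side of the threshold, 130 passed it newly and 16 turned direction.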

Other observations

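All tests in this part, and the genes named in it, were chosen after the results were seen. The genes in this paragraph were picked by hand among those whose groups did not overlap, form no tested group, and did not pass limma's test over all genes. CD80, a ligand that costimulates T cells, was at 18.4 ± 0.992 FPKM in shControl and 37.3 ± 3.85 in shFOXM1 (n = 2 each), and EBI3, a cytokine subunit, at 119 ± 16.9 and 254 ± 31.6 FPKM. SQSTM1, an autophagy receptor, was at 32.9 and 38.2 FPKM in the shControl libraries and at 65.8 and 130 FPKM in shFOXM1 1 and 2. The nuclear RNA NEAT1 was at 20.4 ± 1.98 and 38.6 ± 4.74 FPKM, LMNA, which encodes nuclear lamins, at 92.6 ± 2.8 and 169 ± 25.3 FPKM, and ACTB, an actin often used as a reference gene, at 1410 ± 23 and 2170 ± 296 FPKM. On the lower side PTMA, a prothymosin, was at 602 ± 12.2 and 318 ± 33.1 FPKM and CBX5, a heterochromatin protein, at 7.23 ± 0.0294 and 3.48 ± 0.244 FPKM. The chemokine CCL22, a member of the NF-kB list, was at 3.34 and 4.4 FPKM in shControl 1 and 2, 11 in shFOXM1 1 and 83.9 in shFOXM1 2.

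Several genes of T cells and antigen presentation, and the cell cycle inhibitor CDKN2A, were listed at 0 or nearly so in every library. CD4 and CDKN2A were listed at 0 in all 4 libraries, as were HLA-DRA, HLA-DRB1, HLA-DQA1 and HLA-DQB1, while their partner CD74 was at 1160 ± 48.8 FPKM in shControl and 1360 ± 220 in shFOXM1. HLA-DPA1 was at 154 ± 5.82 and 160 ± 14 FPKM. CD3E had 4, 2, 1 and 6 reads, while CD3D was at 122 ± 5.33 and 125 ± 41.9 FPKM. As the aligner and counter are not given, values at or near 0 cannot be told apart from reads lost in mapping. Among 12 transcription factor families named in the table with at least 10 measured genes, camera called ARID higher (median log2 fold change 0.31, adjusted p = 0.000937) and ETS lower (-0.29, adjusted p = 0.0352), with adjusted p = 0.627 and 0.794 with an estimated correlation.

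The differences of the 2 shFOXM1 libraries from control were correlated over genes when no library was used for both. Over 7241 genes with a mean of at least 5 FPKM, the difference of shFOXM1 1 from shControl 1 and that of shFOXM1 2 from shControl 2 had a Pearson r of 0.446 and a Spearman rho of 0.45, and with the controls exchanged 0.421 and 0.437. These are across genes, which are not independent replicates. Whatever the 2 shControl libraries have in common enters both differences and would also correlate them. The values therefore cannot show that the shFOXM1 libraries share an effect of knockdown.

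The shFOXM1 libraries also differed from each other: 153 such genes differed by at least 1 on the log2 scale, against 22 between the shControl libraries, and over the 7241 genes the SD of the difference was 0.39 against 0.167. A trend with gene length is argued against, since it explained 0.0744% of the variance of the shFOXM1 difference (bootstrap 95% interval 0.0408 to 0.497). Of the 153 genes, 28.1% lay on opposite sides of the controls, YAP1 and ARRDC3 among them, and 33.3% of the 126 with at least 100 reads on average. The exact 95% interval, 21.1 to 35.9, takes genes as independent. A response that moves each gene one way as FOXM1 falls does not describe the genes on opposite sides. Whether a response graded by the remaining FOXM1 is the sole cause is not decided. The 153 genes were picked for differing between these libraries, and the share that spread alone would give was not computed. Of the other 110 genes, shFOXM1 2, with less FOXM1, lay further from the controls for 77. A graded response would give this, but so would any other cause that moves shFOXM1 2 further. Over all genes tested shFOXM1 2 was also the more distant library. The SD of its log2 difference from shControl 1 and 2 was 0.476 and 0.468, against 0.388 and 0.391 for shFOXM1 1. The count therefore cannot tell whether a graded response accounts for part. Different hairpins or culture conditions were not tested.

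The glycolysis and hypoxia list was lower mainly in shFOXM1 2, where HILPDA, a gene that hypoxia induces, was at 4.85 FPKM against 17.3 in shFOXM1 1 and 66.5 and 29 in shControl 1 and 2. The list median stayed at -0.443 or lower under quantile normalization and scaling by recovered reads. These moved the median of all genes by at most 0.047 in any library. They could therefore hardly have removed the fall, and the choice among these scalings does not account for it. Cultures that differ in their hypoxia response apart from the hairpin are a candidate explanation: the list also differed between the shControl libraries, by a median of -0.136, at the 0.01 percentile of 10000 random lists matched on expression, the smallest they can give. That gap is smaller than the list's -0.74 in shFOXM1 2, and random lists do not share regulation as this one does. An effect of FOXM1 knockdown stays open and untested.

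Histone cluster genes were higher while S phase genes were lower. Of 19 with at least 10 reads in at least 2 libraries, 16 were higher in both shFOXM1 libraries than in both shControl libraries, and 0 were lower. Of all 14124 genes with as many reads, 26.9% were higher in this way. Without any effect the share is 16.7% if all libraries vary alike, which they did not. All histone cluster genes together held 624 and 699 reads in shControl and 1660 and 2380 in shFOXM1. Reads moving between near-identical copies are argued against by the total of the 71 genes, which was at least 1.274 higher on the log2 scale in each shFOXM1 library. Carry-over of RNA without a poly(A) tail stays open: the share of reads in short non-coding RNA moved by -0.298 on the log2 scale, while MALAT1, a long RNA without a usual poly(A) tail, was at 14.5 and 16.8 FPKM in shControl and 22.9 and 32.4 in shFOXM1, and NEAT1 was also higher. An effect of FOXM1 knockdown stays open and untested.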
